A study of Mus musculus with 6 samples.

How the data were processed

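Liver RNA of male A/JCr mice, an inbred albino strain, was measured on 6 Affymetrix expression arrays of 45101 probe sets each. Per the labels, the arrays fell into 3 groups of 2 biological replicates: intact uninfected, castrated uninfected, and castrated and infected with Helicobacter hepaticus, a bacterium that colonises the gut and liver of mice. Per the labels and the series' design, inoculation took place at 4 weeks, castration at 12 months and necropsy at 21 months. RNA was extracted with the Qiagen RNeasy kit and labelled as biotinylated cRNA, per the labels' protocols. Intact infected livers were not analysed here, so infection was compared within castrates.

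The deposited values were probe set intensities made with RMA, per the submitters' processing notes. RMA corrects the background, normalizes probe intensities between arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here. The deposited intensities were on a linear scale, as the values showed: they ran from 7.11 to 35659.5, and the log2 of 100% of them lay within 1e-06 of a number with 3 decimals. The array medians ran from 25.04 to 26.2 intensity units. A change shared by most genes would not be seen after such a normalization. The table holds no detection calls. Its 27 control probe sets for Bacillus subtilis genes lay between 3.06 and 5.50 log2 units, and the sources used here do not say whether their transcripts were added. The brightest on each array (5.01 to 5.50, against 4.12 to 4.40 for the next) was taken as an upper level of background, chosen after the data were seen. Where neither array of a gene's lower group exceeded it, the fold is given as a lower bound, the mean of the higher group minus the mean of that level, and no bound is given where an array of the higher group also lay at or below it. The number of arrays limits the precision of every value.

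Probe sets were named through the platform's annotation. Of the 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. The Entrez identifiers of 34741 of the probe sets with 1 symbol were found in a mouse gene table of assembly GRCm38.p6, and 0 symbols needed an update. Each of 18193 genes was represented by its probe set with the highest mean log2 value over the 6 arrays, among probe sets with exactly 1 symbol. Probe sets of several genes were tested without a gene name. Genomic positions are not given, because the sources used here name no genome build for the arrays.

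The log2 of each deposited intensity was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), with 1 mean per group over all 6 arrays and no covariate. The fit left 3 residual degrees of freedom, and the prior added 3.54. Castration was tested as castrated uninfected minus intact uninfected, infection as castrated infected minus castrated uninfected, and both together as castrated infected minus intact uninfected. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18193 genes. Every adjusted p of a gene comes from limma. Errors of fold changes are standard errors from the fit, with n = 2 arrays per group and a residual spread pooled over all 6 arrays. An exact two-sided permutation test of 2 arrays against 2 cannot go below p = 0.333, so no such test was used.

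The text names 27 gene lists of liver functions, cell types and other tissues, with 613 members of which 546 were measured. Each list was tested in each comparison with camera of limma at the preset correlation of 0.01 between genes, adjusted over the 27 lists. The tests were repeated with the correlation estimated from the data and with fry, which asks whether the genes of a list move, on balance, one way. The shift of a list is the median log2 fold change of its measured members. Members called were counted over all genes and adjusted over the list alone. None of the lists was chosen on these samples.

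Genes were named by a fixed rule. It took a panel of 20 genes of sex-specific liver expression and growth hormone signalling whatever their result, the 8 called genes with the largest rise and the 8 with the largest fall per comparison, and up to 4 members of each called list with the smallest p. Where fewer than 8 genes were called, those with the next smallest p were added as values that did not pass. Of the panel, 15 genes are reported, though not each in every comparison, and the others were not analysed here. The groups, tests, lists, naming rule and other settings were fixed before the data were examined.

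The other settings changed 1 choice at a time: quantile normalization again, centring on the array median, a filter at a log2 value of 4.68 (the median of all probe sets, which left 12216 genes), an offset of 16 on the intensities, other rules for the probe set of a gene, another prior, array weights, the replicate number as a block, only the groups compared, other thresholds, and each array left out in turn. The fit was tested on simulated arrays drawn from the fitted prior, with 200 of 18193 genes changed and 10 draws per comparison. For castration it recovered 62.1% of genes changed by 1 log2 unit and 96.4% of those changed by 2, with 5.70% of the calls false. For infection it recovered 60.7% and 96.8%, with 5.31% false, and for both together 65.1% and 96.9%, with 4.66% false. Camera called 100% of 100 simulated lists of 25 genes shifted by 0.5 log2 units and 2% of unshifted ones. The fitted prior sets the spread gene by gene, so these rates need not hold for lists whose members move together. The estimated correlation was 0.79 for antigen presentation, 0.70 for the interferon and 0.77 for the macrophage list. Nor need any rate of the simulation hold where groups differ in spread. Replicates differed by more than 1 log2 unit in 595 genes in the castrated infected group, against 65 (intact) and 58 (castrated uninfected). Figures were drawn with matplotlib 3.10.9.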

Results

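Gene expression was measured in 6 livers of male A/JCr mice at 21 months of age. The 2 intact uninfected, 2 castrated uninfected and 2 castrated infected livers gave 45101 probe set intensities each, with array medians between 25.04 and 26.2. Fold changes are differences of group means of log2 intensity ± SE from limma, with n = 2 arrays per group.

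Arrays of a group resembled each other in the 2 uninfected groups, while 1 castrated infected array stood apart. Over 18193 genes, Pearson's r was 0.996 between the intact arrays, 0.994 between the castrated uninfected arrays and 0.985 between the castrated infected arrays. Castrated infected replicate 1 was closer to the castrated uninfected arrays (0.994 and 0.992) than to replicate 2 of its own group. These correlations are across genes, which are not independent replicates. Castrated infected replicate 2 scored 53.5 on the first principal component (58.1% of the variance), against 7.97 for replicate 1 of its group and −25.7 to −5.03 for the 4 uninfected arrays. The replicates differed by more than 1 log2 unit in 65 genes in the intact group, 58 in the castrated uninfected group and 595 in the castrated infected group. Xist and Y-linked genes had list medians of −0.06 in castration, 0.03 in infection (mean 0.0057, with a test that pointed down) and −0.07 in both together. Camera did not call the list, and 0 of 4 measured members were called over all genes or adjusted over the list alone. These values compare groups, so they cannot show the sex of the animals. Of the 4 members, 2 did not exceed the bacterial controls on any array. The actin 3′ minus 5′ difference, a measure of RNA degradation, lay between 0.556 and 1.083 log2 units, lowest in castrated infected replicate 2. The 18S 5′ control signal was 12.87 and 12.71 in intact, 12.04 and 10.66 in castrated uninfected, and 11.92 and 10.40 in castrated infected arrays. The brightest of 27 control probe sets for bacterial genes lay between 5.01 and 5.50 log2 units on the 6 arrays. A fold is given as a lower bound against that level where neither array of the lower group exceeded it.

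The comparison of castrated with intact uninfected males asked what loss of the testes did to the sex-specific expression of the old liver, the subject the series names. As lists, male-biased liver genes had a median of −1.70 log2 units and female-biased genes one of 1.77, which camera called at its preset correlation (adjusted p = 0.124 and 0.111 with an estimated correlation). Hsd3b5, a steroid-metabolising enzyme of male liver (1420531_at), fell by 7.16 ± 0.56 log2 units, or at least 64.2-fold, from 11.20 to 4.05 (adjusted p = 0.0184). Sult2a2, a hydroxysteroid sulfotransferase (1419528_at), rose by 9.37 ± 0.25 log2 units, or at least 302-fold, from 4.18 to 13.56 (adjusted p = 1.27e-04). Markers of macrophages, antigen presentation and the interferon response were also called higher, with medians of 0.60, 0.58 and 0.44 (adjusted p = 0.609, 0.432 and 0.601 with an estimated correlation).

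In the male-biased list, 8 of 20 measured members fell over all genes and 16 fell when adjusted over the list alone, with 18 of 20 below 0. The organic anion transporter Slco1a1 (1420379_at) fell by 6.29 ± 0.25, or at least 69.3-fold (adjusted p = 9.31e-04). The fatty acid elongase Elovl3 (1420722_at) fell by 5.18 ± 0.39 (adjusted p = 0.0160), and the complement component C6 (1449308_at) fell by 2.53 ± 0.20 (adjusted p = 0.0185). Cyp7b1, an oxysterol hydroxylase of the alternative bile acid pathway (1421074_at), fell by 1.90 ± 0.22 (adjusted p = 0.0468), and its 3 probe sets ran from −1.96 to −0.14. The probe set at −0.14 was dim (mean log2 3.57). Cyp2d9, a cytochrome P450 gene, fell by 2.60 ± 0.22 and Susd4 fell by 2.57 ± 0.23. Cyp4a12a, an arachidonate-metabolising P450, had a value of −4.36 ± 0.53 and did not pass (adjusted p = 0.0533). Camera called the list lower, and the call was lost at adjusted p = 0.124 with an estimated correlation. Fry called it (adjusted p = 0.0326).

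In the female-biased list, 4 of 29 measured members rose over all genes and 24 rose when adjusted over the list alone, with 26 of 29 above 0. Besides Sult2a2 these were Prom1, a membrane glycoprotein also used as a ductular marker (1419700_a_at, 4.87 ± 0.41, adjusted p = 0.0205), the transporter Slc22a27 (1419751_x_at, 3.77 ± 0.42, adjusted p = 0.0419) and the transcriptional regulator Trim24 (1427258_at, 1.66 ± 0.14, adjusted p = 0.0205). The 3 probe sets of Trim24 ran from 0.07 to 1.66. The P450 genes Cyp2b13, Cyp3a44, Cyp2b9 and Cyp17a1 had values of 4.32, 2.21, 2.17 and 1.26 that did not pass over all genes (adjusted p = 0.0799, 0.0799, 0.321 and 0.538). Camera called the list higher, and the call was lost at adjusted p = 0.111 with an estimated correlation. Fry called it (adjusted p = 0.0246), and of the 27 lists it called no others than these 2.

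**Figure D1:**
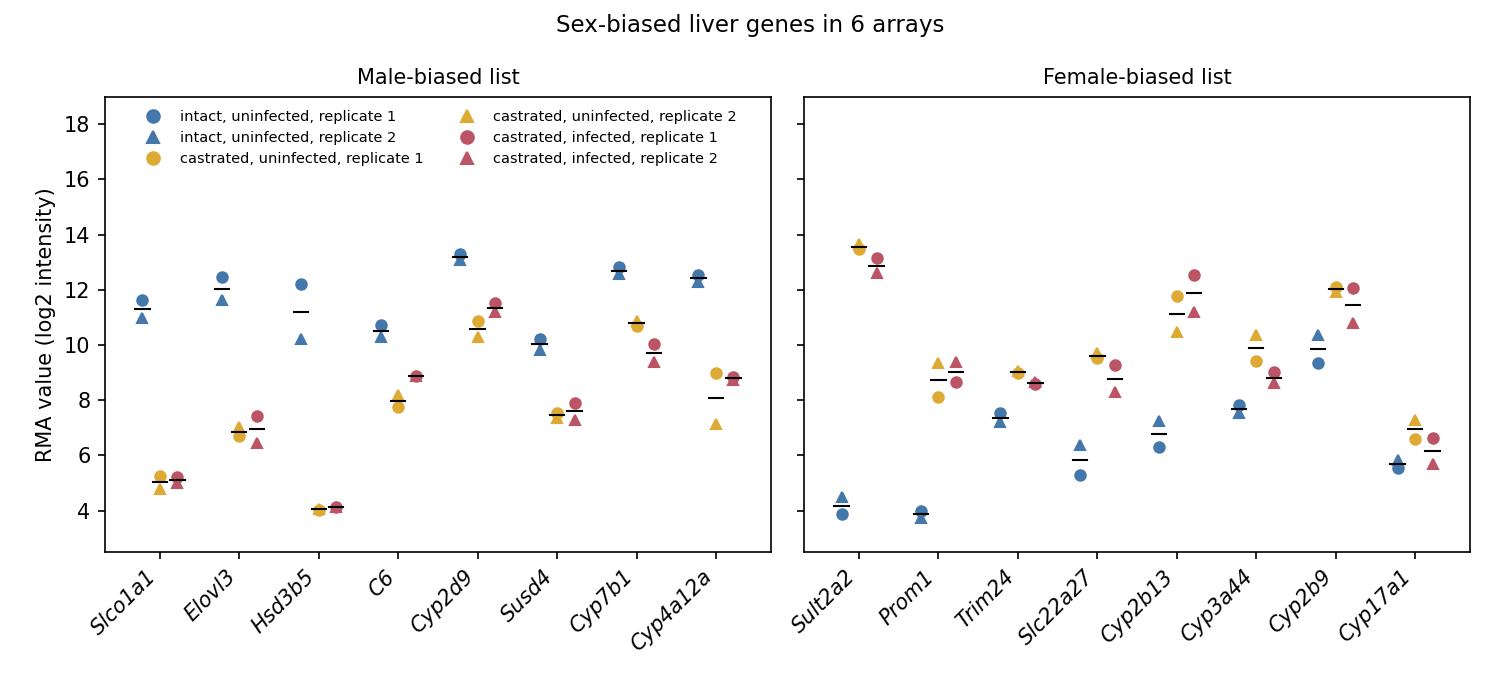
Log2 RMA intensity (y axis) of the 8 named members with the smallest p in castration from the male-biased list (left) and the female-biased list (right), in each of the 6 arrays. Points are single arrays, coloured by group and shaped by replicate, and bars are group means: the mean of Slco1a1 was 11.31 in intact livers against 5.02 and 5.12 in castrated uninfected and castrated infected livers, and that of Sult2a2 was 4.18 against 13.56 and 12.87.

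The list of growth hormone and sex steroid signalling was not called, with 0 of 22 measured members called over all genes and 1 higher when adjusted over the list alone. Its median was −0.01 and its mean 0.03, and the test pointed down. The growth hormone receptor gene Ghr and its target Igf1 had values of −0.19 ± 0.21 and −0.04 ± 0.20 (adjusted p = 0.950 and 0.991). Socs2, a feedback inhibitor of growth hormone signalling, had a value of 0.91 ± 0.40 (adjusted p = 0.838). The repressor gene Bcl6 had −1.76 ± 0.98, with intact arrays at 6.70 and 9.23 and castrated arrays at 7.27 and 5.14, and the repressor gene Cux2, a member of the female-biased list, had 0.14 ± 0.12 on its brightest probe set. The 3 probe sets of Cux2 ran from 0.14 to 1.86, and the 6 of Socs2 from −0.06 to 0.91.

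Other genes with large changes in castration fell outside the lists. Csad, an enzyme of taurine synthesis (1427981_a_at), fell by 3.09 ± 0.16 (adjusted p = 0.00269), and the acetyltransferase gene Nat8 (1419520_at) fell by 2.84 ± 0.32 (adjusted p = 0.0420). Eci3, a fatty acid isomerase (1451588_at), rose by 3.17 ± 0.30 (adjusted p = 0.0296). Rtn4, Rad51b, Nt5e and Cyp2g1 rose by 2.52, 2.43, 2.18 and 2.02. The 5 probe sets of Rtn4 ran from −0.15 to 2.69, the 2 of Rad51b from 0.07 to 2.43 and the 3 of Nt5e from 0.02 to 2.18. The lowest of Rtn4 and of Rad51b were dim (mean log2 4.00 and 3.97). In all 34 called genes the 2 castrated arrays lay on 1 side of the 2 intact arrays.

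Immune lists shifted upward in castrated uninfected livers without a member called over all genes. Antigen presentation had a median of 0.58, with 17 of 17 members above 0 and 7 of them higher when adjusted over the list alone, and camera called it. That call was lost at adjusted p = 0.432 with an estimated correlation. H2-Ab1 and H2-Aa, genes of MHC class II, each had a value of 1.76 (adjusted p = 0.206 and 0.254). The 4 probe sets of H2-Aa ran from −0.11 to 1.89, the lowest being a dim one (mean log2 3.32) and the others at 1.25 or more. The interferon response list had a median of 0.44, with 3 members higher when adjusted over the list alone, and camera called it, but not at adjusted p = 0.601 with an estimated correlation. Its Gbp2, an interferon-induced GTPase gene, had 2.12 ± 0.31 (adjusted p = 0.0925). Macrophage and Kupffer cell markers had a median of 0.60, with 0 members called over all genes or adjusted over the list alone, and camera called the list, but not at adjusted p = 0.609 with an estimated correlation. Their median above the intact mean was 0.34 in castrated uninfected replicate 1 and 0.99 in replicate 2, with values of 1.00 ± 0.25 for Vsig4 and 0.77 ± 0.22 for Clec4f, both Kupffer cell genes. The acute phase list was also called by camera, with a median of 0.35 and 2 members higher when adjusted over the list alone, but not at adjusted p = 0.485 with an estimated correlation. Its metallothionein genes Mt1 and Mt2 had values of 3.53 ± 0.49 and 4.13 ± 0.66 that did not pass (adjusted p = 0.0800 and 0.134), and the 2 probe sets of Mt1 had 0.35 and 3.53. The 18S 5′ signal was lowest among the uninfected arrays in castrated uninfected replicate 2 (10.66), where the macrophage median was the higher. The acute phase median was 0.17 without intact replicate 1 and 0.53 without castrated uninfected replicate 1, and the macrophage median was 0.99 without castrated uninfected replicate 1 and 0.34 without replicate 2.

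Smaller upward shifts were called by camera for 3 lists of other liver cells and for cell division, none with a member called over all genes or adjusted over the list alone. Endothelial markers had a median of 0.22 (adjusted p = 0.124 with an estimated correlation). T and NK cell markers had a median of 0.13 (adjusted p = 0.238 with an estimated correlation), matrix and stellate cell markers one of 0.12 and the cell cycle list one of 0.13 (each adjusted p = 0.694 with an estimated correlation). The T and NK call was lost without intact replicate 1 (0.11), the cell cycle call without intact replicate 1 (0.12) or castrated uninfected replicate 1 (0.16), and the matrix call without intact replicate 2 (−0.005) or castrated uninfected replicate 1 (0.11), while the matrix median was 0.36 without intact replicate 1 and 0.26 without castrated uninfected replicate 2.

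Lipid synthesis genes were higher as lists after castration. Lipogenesis had a median of 0.34, with 17 of 18 members above 0, 0 called over all genes and 6 higher when adjusted over the list alone, and cholesterol biosynthesis had a median of 0.24, with 0 and 3. Camera called both, and both calls were lost at adjusted p = 0.170 with an estimated correlation. Thrsp, a regulator of fatty acid synthesis, had a value of 1.89 ± 0.24 (adjusted p = 0.0660), and Acacb, an acetyl-CoA carboxylase gene, had 1.48 ± 0.29. The 3 probe sets of Thrsp ran from 0.41 to 2.06, and the 2 of Acacb had 0.34 (a dim one, mean log2 4.34) and 1.48. The circadian clock list moved beside them with members in both directions. It had a median of 0.21 and was not called, but when adjusted over the list alone 4 members rose and 4 fell. Without intact replicate 2 the cholesterol median was 0.40, and the clock list was called at 0.40.

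The remaining lists were not called in castration. In cholangiocyte and ductular markers (median 0.05), Prom1 and Pkhd1, a gene of the primary cilium, were called over all genes and adjusted over the list alone, Pkhd1 with 1.14 ± 0.12. In bile acid synthesis and transport (median −0.14) and in pancreas, gut and adipose markers (median 0.08, mean −0.06) only Cyp7b1 and Cela1, an elastase gene that fell by 1.81 ± 0.16, were called in either way. Xenobiotic metabolism and NRF2 targets (median −0.06) had 1 member higher and 2 lower when adjusted over the list alone. No member was called in either way in 8 lists, namely hepatocyte core genes (median 0.06), fatty acid oxidation and PPARalpha targets (median −0.03, mean 0.0013), B and plasma cell markers (0.04), neutrophil markers (0.12), fetal liver and liver tumour genes (median −0.02, mean 0.17), unfolded protein and stress response (0.13), immediate early genes (0.06) and erythroid markers (0.09). The fetal gene Afp had a value of 0.18 ± 0.13 and exceeded the bacterial controls on 1 of the 6 arrays. Calls appeared without 1 array for bile acid synthesis (−0.18, without intact replicate 1), neutrophil markers (0.19 without intact replicate 2 and 0.33 without castrated uninfected replicate 1), and B cell, cholangiocyte and unfolded protein lists (0.08, 0.08 and 0.24, without castrated uninfected replicate 2).

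Over all genes, limma called 15 genes higher and 19 lower in castration, while 551 and 562 had an unadjusted p under 0.05, against 909.65 in all by chance. The groups did not overlap in 40.8% of genes, against 33.3% by chance. These counts rest on single arrays: they were 1 and 3 without intact replicate 1, 3 and 6 without intact replicate 2, 5 and 6 without castrated uninfected replicate 1, 1 and 3 without castrated uninfected replicate 2, and 62 and 38 without either castrated infected array. The castrated infected arrays enter this comparison only through the residual spread pooled over the 3 groups. Their replicates differed by more than 1 log2 unit in 595 genes, against 65 and 58 in the groups compared. Errors and missed calls in castration thus rest partly on arrays outside the comparison. With an offset of 16 on the intensities 5 of the 34 calls were kept, with the mean of all probe sets 21 and with the replicate block 20. The lower group of Prom1, Eci3 and Rad51b did not exceed the bacterial controls on either array, so their changes were at least 10.6-fold, 4.81-fold and 3.91-fold. For Slc22a27 and Nebl this held on 1 of the 2 arrays.

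Infection with H. hepaticus was compared among castrated males. Cyp2d12, a cytochrome P450 gene (1435853_at), rose by 2.31 ± 0.17 log2 units (adjusted p = 0.0418). Casp1, the inflammatory caspase (1449265_at), rose by 1.94 ± 0.16 (adjusted p = 0.0418), and Igha, the constant region of IgA (1421653_a_at), rose by 2.05 ± 0.18 (adjusted p = 0.0498). Noct, a gene with a daily rhythm in liver (1425837_a_at), fell by 2.44 ± 0.18 and Lrrc28 (1433858_at) fell by 1.31 ± 0.11 (adjusted p = 0.0418 each). The 3 probe sets of Lrrc28 ran from −1.31 to −0.13, the one at −0.13 being dim (mean log2 4.03). All 5 calls were lost, with their direction kept, after quantile normalization again, a filter at the median probe set, an offset of 16, array weights or the replicate block. Camera called interferon, antigen presentation, macrophage, matrix and cell cycle lists higher, with medians of 0.53 to 1.01 (each adjusted p = 0.342 with an estimated correlation), and the circadian clock list lower, with a median of −0.57 (adjusted p = 0.264 with an estimated correlation).

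The 3 largest list medians in infection were of immune lists, with no member called over all genes, and fry called 0 of the 27 lists. The macrophage list had a median of 1.01, with 24 of 25 members above 0 and 0 higher when adjusted over the list alone. The interferon list had a median of 0.86, with 26 of 27 above 0 and 1 higher when adjusted over the list alone, and antigen presentation had a median of 0.74, with 17 of 17 above 0 and 10 higher when adjusted over the list alone. Camera called all 3, and each call was lost at adjusted p = 0.342 with an estimated correlation. Psmb9, an immunoproteasome gene, had a value of 1.05 ± 0.16 (adjusted p = 0.234), and Igtp, an interferon-inducible GTPase gene, had 1.35 ± 0.26. C1qc, a complement gene of macrophages, had 1.18 ± 0.36. Above the intact mean, the median was 1.14 in castrated infected replicate 1 and 2.24 in replicate 2 for macrophages, 0.90 and 2.30 for the interferon response, and 1.14 and 1.58 for antigen presentation, while the 18S 5′ signal was 11.92 and 10.40 in these arrays. Without castrated infected replicate 2 the infection medians of the macrophage and interferon lists were 0.41 and 0.46, without castrated infected replicate 1 the interferon median was 1.43, and without castrated uninfected replicate 1 the macrophage median was 0.59.

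Lymphocyte and neutrophil lists shifted less, and 15 of 24 T and NK, 9 of 18 B and plasma cell and 5 of 13 neutrophil members did not exceed the bacterial controls on any array. T and NK cell markers had a median of 0.18 with 0 members higher when adjusted over the list alone, and camera called them, but not at adjusted p = 0.264 with an estimated correlation. Ccl5, a T cell chemokine, had 2.13 ± 0.75. B and plasma cell markers had a median of 0.15 with 5 higher when adjusted over the list alone, and camera called them, but not at adjusted p = 0.342 with an estimated correlation. Among these were Blnk, a B cell adaptor (1.46 ± 0.24), and Jchain, the joining chain of secreted immunoglobulin (0.95 ± 0.17). Neutrophil markers had a median of 0.36 and 0 higher, with a camera call that was lost at adjusted p = 0.598 with an estimated correlation. That call was lost without castrated infected replicate 2 (0.004) and without castrated uninfected replicate 1 (0.15), and the median was 0.67 without castrated infected replicate 1. The B and plasma cell median was 0.07 without castrated uninfected replicate 2.

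Lists of matrix, proliferation and tumour genes also shifted upward in infection, 0 members being called over all genes. Matrix and stellate cell markers had a median of 0.54 with 0 members higher when adjusted over the list alone, and the cell cycle list had a median of 0.53 with 5, and camera called both, but not at adjusted p = 0.342 with an estimated correlation. Col3a1, a fibrillar collagen gene, had 1.64 ± 0.45, and Ube2c, a ubiquitin-conjugating gene of mitosis, had 1.73 ± 0.29. Fetal liver and liver tumour genes had a median of 0.47 with 1 member higher when adjusted over the list alone, and camera called them, but not at adjusted p = 0.264 with an estimated correlation. Its Tff3, Tspan8 and Scd2 had values of 2.76 ± 0.81, 2.65 ± 0.52 and 2.51 ± 0.69, while Afp had −0.10 ± 0.13. The 5 probe sets of Tspan8 ran from 0.03 to 2.65 and the 5 of Afp from −0.10 to 0.88. Immediate early genes (median 0.47; adjusted p = 0.435 with an estimated correlation), cholangiocyte markers (median 0.13; adjusted p = 0.268 with an estimated correlation) and endothelial markers (median 0.14; adjusted p = 0.305 with an estimated correlation) were called higher with 0 members adjusted over the list alone. The cell cycle median above the intact mean was 0.32 in castrated infected replicate 1 and 1.01 in replicate 2. Without castrated infected replicate 2 the matrix and cell cycle medians in infection were 0.34 and 0.16 and the immediate early call was lost at 0.155, and without replicate 1 the cell cycle and immediate early medians were 0.95 and 0.94. The endothelial call was lost without castrated uninfected replicate 1 (0.014) or castrated infected replicate 1 (0.016), and the cholangiocyte median was 0.22 without castrated uninfected replicate 2.

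**Figure D2:**
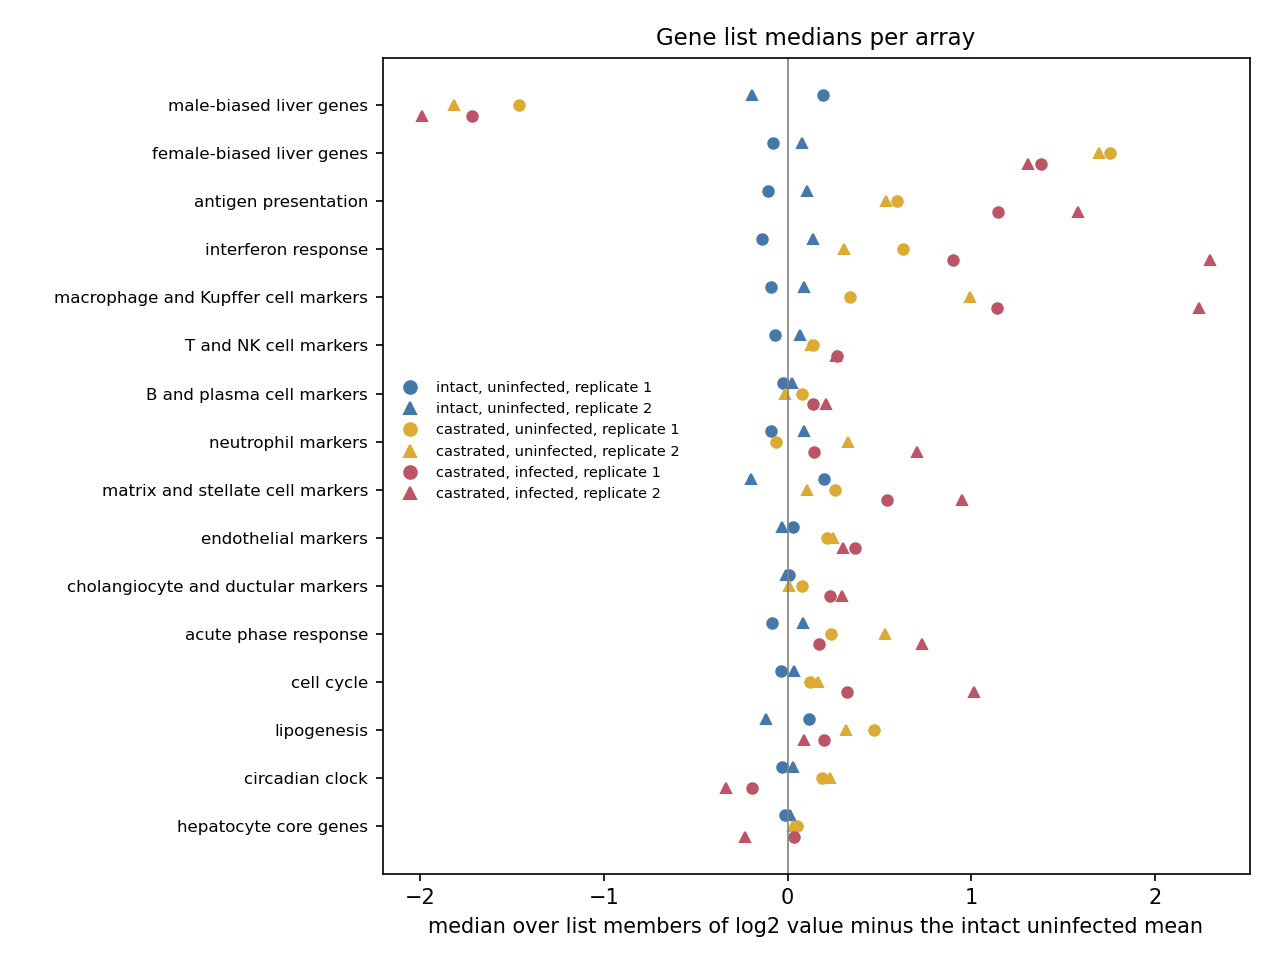
Median over the measured members of 16 gene lists of the log2 value minus the intact uninfected mean (x axis), for each of the 6 arrays. Points are single arrays, coloured by group and shaped by replicate: the interferon median was 0.90 in castrated infected replicate 1 and 2.30 in replicate 2, and the male-biased median lay between −1.99 and −1.46 in all 4 castrated arrays.

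Among male-biased genes, Slco1a1, Elovl3 and Hsd3b5 had values of 0.10 ± 0.25, 0.09 ± 0.39 and 0.08 ± 0.56 in infection, but Slco1a1 and Hsd3b5 did not exceed the bacterial controls in any castrated array. The male-biased list was not called, with a median of 0.07, a mean of −0.05, 0 members called over all genes, and 3 higher and 2 lower when adjusted over the list alone. Female-biased genes had a median of −0.40, with 0 called over all genes and 1 higher when adjusted over the list alone, and camera called the list lower, but not at adjusted p = 0.342 with an estimated correlation. Cyp3a44 and Acot3, an acyl-CoA thioesterase gene, had values of −1.07 ± 0.31 and −1.40 ± 0.42, and Cyp2b13 had 0.77 ± 0.59. Cyp2b9 and Cyp17a1 had −0.59 and −0.78, while the male-biased Cyp4a12a had 0.73. The 3 probe sets of Cux2 ran from −1.60 to −0.37. The female-biased call was lost without castrated infected replicate 2 (−0.15), and the median was −0.61 without replicate 1.

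The circadian clock list shifted downward in infection, with 15 of 18 members below 0, 0 called over all genes, and 7 lower and 2 higher when adjusted over the list alone. Camera called it, but not at adjusted p = 0.264 with an estimated correlation. The clock repressor genes Per3 and Per2 had values of −1.02 ± 0.13 and −0.64 ± 0.11, and Nr1d2 had −1.34 ± 0.27. Arntl, which drives them, had 1.22 ± 0.29, and the clock output gene Dbp had −4.34 ± 0.96. Both were singled out after their values were seen. The list median was −0.31 without castrated infected replicate 2. Dbp lay at 10.61 and 10.32 in the castrated uninfected arrays, 7.12 and 5.13 in the castrated infected arrays and 6.56 and 9.38 in the intact arrays.

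**Figure D3:**
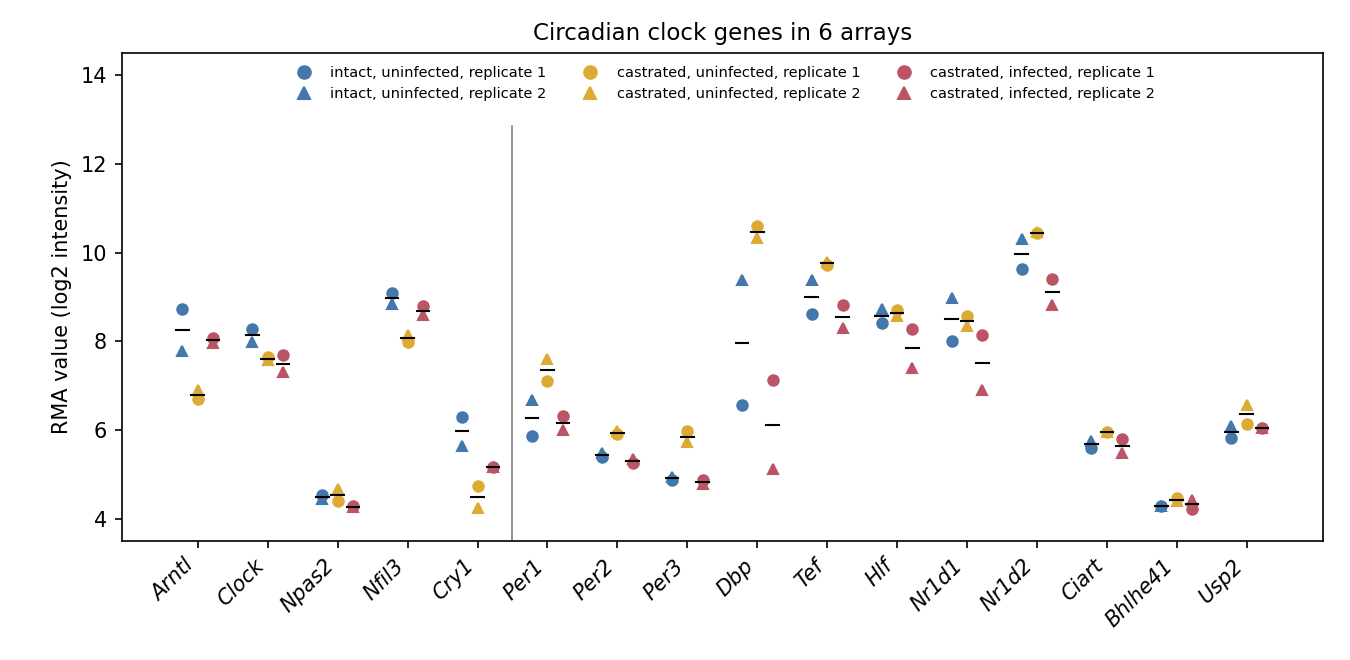
Log2 RMA intensity (y axis) of 16 clock genes in each of the 6 arrays, with 5 genes of the Arntl arm left of the vertical line and 11 of the Per arm to its right. Points are single arrays, coloured by group and shaped by replicate, and bars are group means: Arntl lay at 6.70 and 6.90 in castrated uninfected arrays and between 7.79 and 8.72 in the other 4.

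Metabolic lists moved in both directions in infection, and again no member was called over all genes. Xenobiotic metabolism and NRF2 targets had a median of 0.45 with 5 higher when adjusted over the list alone, among them the glutathione transferase genes Gsta2 (1.13 ± 0.15, adjusted p = 0.195) and Gstm3 (1.91 ± 0.41). Camera called this list, but not at adjusted p = 0.264 with an estimated correlation. Gsta2 had −1.19 in castration and −0.06 in both together, so infected livers lay near the intact level. Gstm3 had −0.18 and 1.74 in the same comparisons. Lipogenesis had a median of −0.28 with 4 lower and 1 higher when adjusted over the list alone, and camera called it lower, but not at adjusted p = 0.305 with an estimated correlation. Thrsp and Me1, the malic enzyme gene, had values of −1.53 ± 0.24 and −0.83 ± 0.11. Bile acid synthesis and transport had a median of −0.29 with 1 lower when adjusted over the list alone (adjusted p = 0.457 with an estimated correlation). Hepatocyte core genes had −0.15 with 0 (adjusted p = 0.435 with an estimated correlation), and fatty acid oxidation and PPARalpha targets −0.17 with 1 higher (adjusted p = 0.582 with an estimated correlation). Camera called each of the last 3 lower. Cyp7b1, the gluconeogenic gene Pck1 and the lipid-sensing receptor gene Ppara had values of −1.08 ± 0.22, −1.20 ± 0.30 and −0.82 ± 0.21. Probe sets ran from −1.18 to 0.11 for Cyp7b1, from −1.30 to −0.04 for Pck1 and from −1.77 to −0.62 for Thrsp. Those at 0.11 and −0.04 were dim (mean log2 3.57 and 3.67). Without castrated infected replicate 2 the xenobiotic median was 0.30 and the bile acid, hepatocyte core and fatty acid oxidation calls were lost at −0.08, −0.025 and −0.02. Without replicate 1 the hepatocyte core and fatty acid oxidation medians were −0.24 and −0.34, and without castrated uninfected replicates 1 and 2 in turn the fatty acid oxidation call (−0.09) and the bile acid call (−0.19) were lost.

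The remaining lists were not called in infection, and no member of them was called over all genes. Growth hormone and sex steroid signalling had a median of −0.06 and a mean of 0.04. Bcl6 had 2.02 on its brighter probe set and 1.33 on the other, against falls in castration. Ghr and Igf1 had −0.34 and −0.25, and the 6 probe sets of Socs2 ran from −0.14 to 0.47. The acute phase list had a median of −0.01 and a mean of −0.04 with a test that pointed up. It was called at medians of 0.26, 0.29 and −0.125 without castrated uninfected replicate 2, castrated infected replicate 1 and castrated infected replicate 2. Medians were 0.09 for cholesterol biosynthesis, −0.14 for the unfolded protein and stress response, −0.08 for pancreas, gut and adipose markers and −0.16 for erythroid markers, of which 1 member was higher when adjusted over the list alone. No other member of these lists was called in that way, and the unfolded protein list was called at −0.15 without castrated uninfected replicate 2 and −0.31 without castrated infected replicate 2. Next to the calls stood Wfdc15b (1.14 ± 0.10, adjusted p = 0.0582), Bnc2, Tmem26, Eif4e3 and Smim22 with values of 1.07, 1.11, 1.73 and 0.96, and Eci3, Vegfb, Nebl and Ppargc1a with values of −2.55, −0.82, −0.79 and −0.95. The 2 probe sets of Smim22 had −0.20 and 0.96, and the 3 of Bnc2 ran from 0.11 to 1.07.

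Over all genes, limma called 3 genes higher and 2 lower in infection, each with both infected arrays beyond both uninfected ones, while 1189 and 832 had an unadjusted p under 0.05. The groups did not overlap in 40.9% of genes, against 33.3% by chance. The counts were 1060 and 513 without castrated infected replicate 1, 4 and 0 without castrated infected replicate 2, and 0 and 0 without any 1 of the 4 other arrays or with only the 2 groups compared. Against the bacterial controls, the lower group of Cyp2d12, Eci3, Tspan8, Tmem26, Per2 and Per3 gave changes of at least 3.73-fold, 4.26-fold, 2.61-fold, 1.68-fold, 1.36-fold and 1.28-fold, and Bnc2 exceeded the controls on no array. Wfdc15b and Ube2c did not exceed them on 1 of the 2 castrated uninfected arrays, and Nebl exceeded them on only 1 of the 4 castrated arrays.

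Castrated infected livers were set against intact uninfected ones to give both factors together, which the arrays analysed here cannot separate in this comparison. Camera called male-biased genes lower, with a median of −1.85 log2 units, and female-biased, interferon and antigen presentation genes higher, with medians of 1.36, 1.80 and 1.29 (adjusted p = 0.118, 0.110, 0.230 and 0.205 with an estimated correlation). The MHC class II genes H2-Eb1, H2-Aa and H2-Ab1 and their invariant chain gene Cd74 rose by 3.23 ± 0.40, 3.22 ± 0.35, 3.15 ± 0.32 and 3.17 ± 0.37 (adjusted p = 0.0407, 0.0278, 0.0249 and 0.0355), and the 4 probe sets of H2-Aa ran from 0.25 to 3.54. Sult1e1, an oestrogen sulfotransferase gene (1420447_at), rose by 3.53 ± 0.47, from 3.66 to 7.19 (adjusted p = 0.0495), with arrays at 7.88 and 6.50 in castrated infected livers. Its intact level did not exceed the bacterial controls, and the rise was at least 3.65-fold.

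In the male-biased list 9 of 20 members fell over all genes and 16 when adjusted over the list alone, with changes of −7.07, −6.20, −5.09 and −2.97 in Hsd3b5, Slco1a1, Elovl3 and Cyp7b1. The call was lost at adjusted p = 0.118 with an estimated correlation. In the female-biased list 5 of 29 rose over all genes and 20 when adjusted over the list alone, among them Sult2a2 (8.69 ± 0.25), Prom1 (5.17 ± 0.41), Cyp2b13 (5.09 ± 0.59) and Atp6v0d2, a proton pump subunit gene (2.16 ± 0.24). That call was lost at adjusted p = 0.110 with an estimated correlation. Fry called both lists (adjusted p = 0.0219 each). Cyp4a12a had a value of −3.62 ± 0.53 that did not pass (adjusted p = 0.0531). Among other called genes, Csad, Susd4, Nebl and Rps4l had changes of −2.35, −2.43, −2.31 and −2.99. Probe sets ran from −2.31 to −0.07 for Nebl and from −3.13 to −0.03 for Cyp7b1. Those at −0.07 and −0.03 were dim (mean log2 3.58 and 3.57).

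In antigen presentation 6 of 17 members rose over all genes and 15 when adjusted over the list alone, including the immunoproteasome gene Psmb9 (1.79 ± 0.16) and the peptide transporter gene Tap2 (1.28 ± 0.14). Its camera call was lost at adjusted p = 0.205 with an estimated correlation, while fry called it (adjusted p = 0.0352). In all, fry called 9 of the 27 lists, and neither the interferon nor the macrophage list was among them (adjusted p = 0.0888 and 0.0922). In the interferon list Gbp2 rose over all genes (3.14 ± 0.31) and 23 of 27 members rose when adjusted over the list alone, with a camera call lost at adjusted p = 0.230 with an estimated correlation. Gbp8, a related GTPase gene, rose by 3.30 ± 0.37. Macrophage markers had a median of 1.61, with 0 called over all genes and 17 of 25 higher when adjusted over the list alone (adjusted p = 0.266 with an estimated correlation). T and NK cell markers had 0.27 with 0 and 7 (adjusted p = 0.110 with an estimated correlation), and B and plasma cell markers 0.20 with 1 and 3 (adjusted p = 0.279 with an estimated correlation), the called gene being Blnk (2.26 ± 0.24). Neutrophil markers had 0.33 with 0 and 1 (adjusted p = 0.484 with an estimated correlation), and the acute phase list 0.46 with 0 and 5 (adjusted p = 0.399 with an estimated correlation), with Lcn2, an iron-binding acute phase gene, at 5.11 ± 1.31. Camera called the last 5 lists higher, and of these fry called the T and NK and the B and plasma cell lists (adjusted p = 0.0319 and 0.0352). Without castrated infected replicate 2 the interferon median was 0.90, the acute phase median 0.17 and the neutrophil call was lost at 0.14, and without replicate 1 the acute phase and neutrophil medians were 0.73 and 0.70.

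Camera also called higher the lists of other cell types and of growth. Matrix and stellate cell markers had a median of 0.79 with 0 members called over all genes and 16 when adjusted over the list alone (adjusted p = 0.230 with an estimated correlation). The cell cycle list had 0.66 with 1, Ube2c (2.27 ± 0.29), and 13 (adjusted p = 0.267 with an estimated correlation). Fetal liver and liver tumour genes had 0.62 with 0, and 10 higher and 1 lower when adjusted over the list alone (adjusted p = 0.110 with an estimated correlation), Afp having a value of 0.07 ± 0.13. Endothelial markers had 0.38 with 0 and 5, and cholangiocyte markers 0.20 with 2, Prom1 and Pkhd1, and 2 (each adjusted p = 0.110 with an estimated correlation). Immediate early genes had 0.52 with 0 and 0 (adjusted p = 0.406 with an estimated correlation). Fry called the endothelial, cholangiocyte, and fetal and tumour lists (adjusted p = 0.0219, 0.0259 and 0.0319). The cell cycle median was 0.32 and the immediate early call was lost at 0.08 without castrated infected replicate 2, and without replicate 1 the cell cycle, fetal and tumour, immediate early and cholangiocyte medians were 1.01, 1.03, 0.81 and 0.30. The immediate early median was 0.27 without intact replicate 1.

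Metabolic lists shifted in both directions in castrated infected against intact livers. Cholesterol biosynthesis (median 0.30, 0 called over all genes and 5 higher when adjusted over the list alone, adjusted p = 0.160 with an estimated correlation) and xenobiotic metabolism (0.34, 0 and 4, adjusted p = 0.184 with an estimated correlation) were called higher, the first also by fry (adjusted p = 0.0332). Bile acid synthesis and transport was called lower, with a median of −0.27, Cyp7b1 called over all genes, 5 lower and 3 higher when adjusted over the list alone, and adjusted p = 0.284 with an estimated correlation. Hepatocyte core genes (−0.17, adjusted p = 0.506 with an estimated correlation), fatty acid oxidation (−0.19, adjusted p = 0.555 with an estimated correlation) and the circadian clock (−0.25, adjusted p = 0.184 with an estimated correlation) were called lower with 0 members in either way. Not called were lipogenesis (0.13, 1 lower when adjusted over the list alone), growth hormone and sex steroid signalling (median −0.02, mean 0.07), unfolded protein and stress response (median 0.06, mean −0.0012), erythroid markers (median −0.13, mean 0.04, 1 higher and 1 lower when adjusted over the list alone) and pancreas, gut and adipose markers (−0.0075, with only Cela1 called in either way, at −1.86). Without castrated infected replicate 2 the xenobiotic and bile acid medians were 0.15 and −0.15 and the hepatocyte core call was lost at 0.03, as it was without intact replicate 1 (−0.10). The fatty acid oxidation call was lost without any 1 of 4 arrays, at −0.04 (castrated infected replicate 2), −0.10 (intact replicate 2) and −0.19 (either castrated uninfected array), and without castrated infected replicate 1 the median was −0.35 and that of bile acid synthesis −0.45. Without intact replicate 1 the cholesterol median was 0.17 and lipogenesis was called at 0.17, and without castrated infected replicate 1 the unfolded protein list was called at 0.22.

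Over all genes, limma called 51 genes higher and 23 lower, in each of which the groups did not overlap, while 1499 and 1202 had an unadjusted p under 0.05. In the F test 41 genes differed among the 3 groups. The groups did not overlap in 47.3% of genes, against 33.3% by chance. The counts were 1332 and 782 without castrated infected replicate 1, 110 and 25 without castrated infected replicate 2, 4 and 6 without either castrated uninfected array, 1 and 2 without intact replicate 1, and 4 and 6 without intact replicate 2. Of the 74 calls, 13 were kept with an offset of 16 and 41 with the mean of all probe sets. Against the bacterial controls, changes were at least 188-fold for Sult2a2, 56.5-fold for Slco1a1, 52.3-fold for Hsd3b5 and 13.1-fold for Prom1, and at least 5.03-fold for Gbp8, 2.88-fold for Blnk, 2.69-fold for Ube2c and 2.15-fold for Nebl.

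Called genes of the castration comparison and of both factors together overlapped in 24 genes. Of these, 9 rose and 15 fell in both, against 0.0420 and 0.0240 for independent lists, and they include Sult2a2, Prom1, Slco1a1, Hsd3b5, Elovl3 and Csad. The intact arrays are shared by the 2 comparisons, so part of the excess may come from them. They were not split between the comparisons, which would leave a lone intact array in each. Fold changes correlated across genes at 0.63, against 0.50 in simulated groups with no effect, and their covariance was 0.0790 against 0.0164. Castration and infection, which share the castrated uninfected arrays with opposite sign, had 0 called genes in common at an adjusted p. Their fold changes correlated at −0.08 against −0.50 in simulated groups, with a covariance of −0.0082 against −0.0164. The simulated groups all had the pooled spread, which sets the correlations near 0.50 and −0.50 whatever the data. In the arrays, spread differed between groups. Replicates differed by more than 1 log2 unit in 65 genes (intact), 58 (castrated uninfected) and 595 (castrated infected). The simulated values are thus no fit baseline for the shared groups, and no conclusion is drawn from the gaps.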

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

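No test in this part was chosen after its result was seen. Probe sets without a gene name of their own were outside the gene comparisons, and some of them passed the threshold. In castration 1 probe set annotated to several genes was called, 1419704_at, with a rise of 4.52 ± 0.14 log2 units from 9.07 to 13.59 (limma adjusted p = 1.53e-04). In the same comparison 4 probe sets annotated to no gene were called, 1 higher and 3 lower, led by 1457263_at with −2.44 ± 0.20 (adjusted p = 0.0229). In castrated infected against intact livers 7 probe sets annotated to several genes were called, all higher, among them 1449009_at with 3.99 ± 0.40 (adjusted p = 0.0211). There were 11 called probe sets annotated to no gene in that comparison, 4 higher and 7 lower, among them 1442537_at with −2.75 ± 0.23 (adjusted p = 0.0128).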

How the results depend on the processing

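All settings below, except the level of background given last, were chosen before their results were seen. The 51 results of named genes past the threshold kept their direction in 816 of 816 alternative values and their call in 516. The kept direction is no test of these genes. The groups did not overlap in any called gene, so leaving out an array or changing the threshold could not turn it. Numbers of called genes moved with the processing, and the causes were not tested beyond what each setting removes. The counts of genes higher and lower were 15 and 19 in castration, 3 and 2 in infection, and 51 and 23 in both together, with 41 in the F test.

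With an offset of 16 they were 1 and 4, 0 and 0, and 7 and 6, with 8. Quantile normalization again, the filter at the median probe set and array weights each left 0 and 0 in infection, and array weights gave 40 higher in castration, 78 higher in both together and 100 in the F test. With the mean of all probe sets 7 genes were higher in castration, 1 lower in infection and 28 higher in both together. Tested singly, 23 probe sets were higher in castration, 1 was lower in infection, 79 were higher and 42 lower in both together, and 68 passed the F test. At an adjusted p under 0.1, 36 were higher in castration, 150 higher and 71 lower in both together, and 113 passed the F test. With only the groups compared the counts were 62 and 38, 0 and 0, and 4 and 6.

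Same-numbered arrays were not treated as pairs in the main fit, and their deviations correlated at 0.12, 0.03 and 0.02 over all genes. Such small correlations cannot exclude a factor shared by same-numbered arrays. The 18S 5′ signal was lower in replicate 2 than in replicate 1 of every group (12.71 against 12.87, 10.66 against 12.04 and 10.40 against 11.92). With the replicate block, counts were 0 and 0 in infection, 132 and 45 in both together and 66 in the F test.

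Leaving out 1 array at a time gave 1 to 62 higher and 3 to 38 lower in castration, 0 to 1060 and 0 to 513 in infection, 1 to 1332 and 2 to 782 in both together, and 3 to 1692 in the F test. Where an array was left out, the lone array of its group was assumed to vary like the others. The acute phase median in infection, −0.01 with no call, ran from −0.125 (called lower without castrated infected replicate 2) to 0.29. The neutrophil median in infection, 0.36, ran from 0.004 to 0.67, and without castrated infected replicate 2 its test pointed down.

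List calls depended on whether the correlation between genes was preset or estimated, and 3 residual degrees of freedom estimate it poorly. Calls were also lost where the estimate did not exceed the preset 0.01. Examples are endothelial markers in castration (−0.029) and fetal and tumour genes in infection (0.0081). A higher correlation therefore does not account for every lost call. The leading lists lost their camera calls with an estimated correlation at unchanged medians: in castration −1.70 (male-biased), 1.77 (female-biased), 0.34 (lipogenesis), 0.58 (antigen presentation), 0.44 (interferon) and 0.60 (macrophage), in infection 0.74 (antigen presentation), 0.86 (interferon), 1.01 (macrophage), 0.54 (matrix), 0.53 (cell cycle) and −0.57 (clock), and in both together −1.85, 1.36, 1.29 and 1.80 (male-biased, female-biased, antigen presentation and interferon). Of these, fry did not call the last 4 in castration, all 6 in infection, or interferon in both together. Over all lists, 1302 values under other settings kept direction and side of the threshold, 131 lost a call, 23 gained one and 2, both given above, turned. Signal over background was judged from bacterial control probe sets, chosen after the data were seen: 36.9% of genes did not exceed the brightest of them on any array.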

Other observations

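The tests of RNA degradation, of the 18S signal and of pancreas, gut and adipose tissue in the infected array, and of the hepatocyte share and of single arrays in castration, were chosen after the results were seen. Castrated infected replicate 2 exceeded replicate 1 by over 1 log2 unit in 485 genes and fell below it in 110. Genes singled out after their values were seen include Spink1, a trypsin inhibitor gene of pancreas and of regenerating or tumour-bearing liver, at 8.66 against 4.04, and Ly6d, a surface antigen gene, at 9.20 against 6.32. Tff3, a gene of gut mucosa, lay at 9.56 against 6.71, Scd2 at 9.65 against 7.18 and the macrophage gene Gpnmb at 7.86 against 5.84. Casp1 and Igha were close in the 2 infected arrays, at 7.60 and 8.01 and at 11.15 and 11.21.

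Acute phase genes differed between replicates. Lcn2 lay at 5.94 and 6.48 in intact, 8.06 and 11.29 in castrated uninfected, and 9.62 and 13.03 in castrated infected arrays. Saa2 lay at 6.97 and 7.80, 8.99 and 11.03, and 8.99 and 10.26 in the same order. The metallothionein gene Mt1 lay at 9.42 and 10.24, 13.00 and 13.73, and 10.99 and 12.33.

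Castrated infected replicate 2 stood apart from the other 5 arrays. RNA degradation with 3′ bias was argued against by an actin 3′ minus 5′ difference of −0.527 relative to the highest of the other arrays, but another difference in RNA preparation or labelling cannot be told apart, since its 18S 5′ signal was lower than in any other array (−0.256 relative to castrated uninfected replicate 2). Admixture of pancreas was argued against, despite the higher Spink1, by its 10 measured markers. None exceeded replicate 1 by more than 0.153, but 5 were not above the bacterial controls on any array. A lower share of hepatocytes cannot be told apart. Marker lists moved apart by 1.08 log2 units, from macrophage (1.05) to endothelial (−0.03), where that share alone would give like medians. The rule set beforehand counted a list median at or below 0 against that share, and the endothelial median met it. Its 95% interval, however, ran from −0.1645 to 0.454. But the bootstrap 95% interval of 0.541 to 1.58, drawn over correlated members, reached the 0.579 and 0.591 between the uninfected replicates. Hepatocyte core genes also lay lower than in replicate 1, with a median of −0.253 (95% interval −0.566 to −0.118). Gut and adipose tissue cannot be told apart, with only 3 and 4 markers and a higher Tff3. The gut markers went both ways: Apoa4 was higher by 1.79, while Vil1 and Fabp2 had differences of −1.35 and −0.294. Gut tissue would have raised each of them. The adipose markers ran from −0.111 to 0.254 (Cidec), and 3 of them did not exceed the bacterial controls on any array. Tumour tissue in the piece may account for it and cannot be told apart, since the tumour list had a median of 0.086 (95% interval −0.169 to 1.46, 7 of its 27 members also in other lists) and the cell cycle list one of 0.674, and a stronger reaction to infection in that animal stays open, untested.

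Antigen presentation, interferon and macrophage lists were higher in castrated than in intact uninfected livers. A single array as the cause was argued against for antigen presentation by its medians over pairs of arrays. The smallest was 0.425, against 0.209 between the intact and 0.078 between the castrated replicates. The 95% lower bounds (0.222 or more) also lay above 0.209. But these bounds resample correlated members (estimated correlation 0.79) as if independent, so they are too narrow and give no spread between animals. For the other lists it cannot be told apart: the smallest median was 0.174 for interferon, under the 0.299 between the castrated replicates, and 0.22 for macrophages, under 0.491. A lower share of hepatocytes cannot be told apart, since the 2 castrated arrays differed. The macrophage median exceeded the matrix median by 0.483 in the group (95% interval 0.0765 to 0.7455). The excess was 0.886 in replicate 2 (0.144 to 1.11), but 0.0823 in replicate 1 (−0.23 to 0.352). Over the endothelial median it was 0.384 in the group (0.00475 to 0.6415), with intervals of −0.172 to 0.337 in replicate 1 and −0.027 to 1.01 in replicate 2. A difference in RNA preparation, the 18S 5′ signal being lower in both castrated arrays, and an effect of castration on liver immunity stay open and were not tested.

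The clock list was lower in castrated infected than in castrated uninfected livers. Castrated infected replicate 2 alone was argued against, since replicate 1 by itself had a median of −0.314, beyond the 0.183 between the castrated uninfected arrays. A different time of day at necropsy is a candidate explanation: the Arntl arm had a median of 0.63 (Clock and Npas2 at −0.11 and −0.27, with Npas2 and Cry1 not above the bacterial controls in any castrated array) while the Per arm had −0.94, and in castration the arms had −0.90 and 0.48. The mean of the Per arm minus that of the Arntl arm was 1.30 and 1.30 in castrated uninfected, −0.05 and −0.42 in castrated infected, and −0.74 and 0.33 in intact arrays. A shift of the clock by infection or castration stays open, as does whether Noct, Thrsp and Eci3 followed it, which was not tested.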
